A study of Rattus norvegicus with 9 samples.

How the data were processed

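Expression was measured in 9 arrays of rat pancreatic stellate cells on 3 culture surfaces. The values are log2 expression values as deposited, which the authors made with RMA (background correction, quantile normalization across the arrays and a summary per probe set), per the submitters' processing notes; the software, its version and the genome build are not given in the sources used here. The log2 unit was checked on the values, which lay between about 1 and 14 with none negative. Nothing was normalized again for the reported values.

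Of 29215 probe set entries, 15310 were paired with exactly 1 gene symbol by the array's probe table, 323 with several symbols and 13582 with none. For a gene with several entries the one with the highest mean over all 9 arrays was kept, which left out 804 and gave 14506 genes tested. A RefSeq gene table held the identifiers of 15279 of the 15310 single-symbol entries and changed 0 symbols. No genome coordinates were used. Probes can also read near-identical relatives of a gene. The deposited values were identical to the last digit given on at least 2 arrays for 8192 genes and on all plastic arrays for 134.

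Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per surface over all 9 arrays (6 residual degrees of freedom), empirical Bayes moderation without trend, and Benjamini-Hochberg adjustment over the 14506 genes within each of the 3 comparisons. A call means a two-sided adjusted p under 0.05. Gene lists were tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over 33 lists of at least 5 tested members, 22 pathway lists and 11 cell type lists; beside it stand an estimated correlation and the self-contained test fry. Of 902 list entries 798 had a tested gene and 104 had none. The model, the threshold, the lists and the rule for naming genes were chosen before the data were examined. The rule named, for each comparison, the 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and 15 stellate cell genes whatever their values: Acta2, Des, Gfap, Vim, Col1a1, Col1a2, Col3a1, Fn1, Timp1, Mmp2, Ccn2, Tgfb1, Pparg, Lrat and Plin2. Predicted genes counted but were passed over when naming, and the text prints a part of the named genes. Gcg, Ins1, Ins2, Adipoq and Rxra in the closing section were chosen after their values were seen.

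The alternatives were re-centring each array on its median, quantile normalization applied again, only genes above the 40th percentile of mean level (log2 4.25), every entry of the value table tested, only the 2 compared groups in the fit, trend and robust moderation, array weights, the title letter as a fixed or a random block, a minimum difference of 2-fold, and leaving out each array in turn. Fitting with only the plastic arrays of letters A and S, and with the macrophage list mean as a covariate, was chosen after seeing the data. Deviations from the group means correlated across genes between collagen and plastic arrays of the same letter (r = 0.196 for A, 0.234 for P and 0.269 for Z). The collagen array of letter A correlated more with the plastic array of letter S (r = 0.243), whereas those of P and Z were highest with their own letter. For Matrigel and plastic the same-letter values were -0.131 for A and 0.406 for S. The deviations of the 2 Matrigel arrays mirror each other, so these values are not separate checks. Letters were read as pairs only for collagen and plastic, a choice that these values do not settle for Matrigel. Differences on both matrices were compared with 100 simulations in which no group differed and both comparisons shared the plastic arrays.

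The replicates may be technical, since the labels do not say whether arrays came from separate animals, so the p-values measure only the spread between these samples. The number of arrays limits the precision. Tested on simulated data with these group sizes, limma recovered 84% of genes changed by 1 on the log2 scale between Matrigel and plastic. It recovered 91% between collagen and plastic, 92% between Matrigel and collagen, and 99% of those changed by 2 in each comparison. False calls numbered 9, 5 and 11 among the unchanged of 14506 genes. The simulated noise was normal at each gene's fitted spread, so these rates hold only under the model's own assumptions. Camera recovered 5 of 5 lists shifted by 0.5 in each comparison and called 0 unshifted lists. The simulated genes varied independently of each other, so these runs do not test list calls where genes are correlated. For a gene with a group mean under log2 4.25 the text prints the distance of the brighter mean from that level as a lower bound. For it each array of the dim group stood at the higher of its value and that level. That bound is for the means of all arrays and has no error of its own, so differences under an alternative can fall below it. Multiples of the fitted difference set a log2 difference under an alternative against that of the reported limma fit, and are printed beside some ended calls and where leaving out 1 array moved a named difference by over 1.5-fold. Both were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.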

Results

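Pancreatic stellate cells are the fibroblast-like cells of the pancreas, which store retinoid in lipid droplets while quiescent and deposit matrix as myofibroblasts once activated. Stellate cells from male Sprague Dawley rats were cultured for 72 hours on uncoated plastic, on Matrigel, a basement membrane extract rich in laminin and collagen IV, or on collagen I, the main fibrillar collagen of scar tissue. Each dish of 10 cm received the same number of cells in medium with 10% serum. Expression was measured on Affymetrix rat whole-transcript arrays, with 4 arrays of cells on plastic, 3 on collagen I and 2 on Matrigel, and the comparisons ask how expression differed between the 3 surfaces. A letter in the sample titles (A, P, S or Z), whose meaning the labels do not state, recurs across surfaces: the plastic arrays carry all 4 letters, the collagen arrays A, P and Z, and the Matrigel arrays only A and S. The array medians lay between 4.08 and 4.18 on the log2 scale. Across all genes, which are not independent replicates, arrays of the same surface correlated at r = 0.991 to 0.996 and arrays of different surfaces at r = 0.975 to 0.989.

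Against plastic, 11 of 26 measured contractile and cytoskeletal genes fell on Matrigel, and of 29 retinoid and lipid storage genes 13 rose and 2 fell. Tagln (Entrez gene 25123), which encodes the actin-binding protein transgelin, averaged 4.13 ± 0.05 (SD, n = 2) on Matrigel and 8.46 ± 1.01 (SD, n = 4) on plastic (adjusted p = 0.00342). Fabp4 (Entrez gene 79451), a fatty acid carrier of adipocytes and macrophages, averaged 7.03 ± 1.49 on Matrigel against 3.25 ± 0.60 on plastic, at least 2.78 higher (adjusted p = 0.00451). Means under log2 4.25, like those of Tagln on Matrigel and of Fabp4 on plastic, are dim. Differences from such a mean are printed only as at least the distance from that level, a distance between means without an error. The largest fall among named genes was that of F3 (Entrez gene 25584), the coagulation initiator tissue factor, which was 34.5-fold lower on Matrigel (adjusted p = 0.000512). Of 14506 genes tested with limma, 1504 differed between Matrigel and plastic, 655 higher and 849 lower on Matrigel, and 431 of them differed by at least 2-fold. With each array re-centred on its own median, which moved the median difference of all genes from -0.01 to -0.07, 512 genes were higher and 1036 lower. Of 33 gene lists, 17 passed by camera with its preset correlation, 10 higher and 7 lower on Matrigel; with a correlation estimated for each list camera called 0, and 3 had an unadjusted p under 0.05. Fabp4 did not pass with the macrophage list mean as a covariate, an alternative chosen after seeing the data (adjusted p = 0.0737), at 0.838 times the fitted difference. Fabp4 lay at 1.28 times the fitted difference without Matrigel replicate 1. Fabp4 lay at 0.721 times the fitted difference without Matrigel replicate 2, which is 2.72 and under the printed 2.78.

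In the contractile and cytoskeletal list, 11 of 26 measured members fell on Matrigel, 16 adjusted over the list alone. The list as a whole was lower than other genes (camera adjusted p = 5.19e-09; adjusted p = 0.365 with an estimated correlation). Tagln fell by at least 4.21, the tropomyosin gene Tpm2 by 2.68 ± 0.23 (log2, SE) and Des, which encodes the intermediate filament protein desmin, by 1.93 ± 0.13. Acta2, which encodes the alpha smooth muscle actin used to mark activated stellate cells, differed by -1.23 ± 0.39 and did not pass (adjusted p = 0.0892). Its probes can also read the near-identical Actg2. Vim, the vimentin gene, differed by -0.36 ± 0.13 (adjusted p = 0.117). Gfap, a marker shared with astrocytes that was dim on both surfaces, did not pass (adjusted p = 0.443). The list mean was lower on Matrigel than on plastic within letter A, by -0.67, and within letter S, by -0.69, against an SD of 0.23 among the plastic arrays. Of 20 targets of the YAP/TAZ and SRF regulators, which respond to cell spreading and tension, 11 fell and 2 rose. The counts adjusted over the list alone were the same (camera adjusted p = 5.46e-05; adjusted p = 0.365 with an estimated correlation). Besides F3, Amotl2 fell by 1.53 ± 0.15 and Gadd45b by 2.08 ± 0.11, whereas the immediate-early gene Egr1 rose by 1.84 ± 0.19. Ccn2, the connective tissue growth factor gene, differed by -1.13 ± 0.52 (adjusted p = 0.232).

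Of 28 fibrillar collagens and collagen-processing genes, 8 fell on Matrigel, 11 adjusted over the list alone with 1 higher (camera adjusted p = 0.000121; adjusted p = 0.365 with an estimated correlation). The cross-linking enzyme gene Loxl1 fell by 1.72 ± 0.33, Col12a1 by 1.62 ± 0.29 and Col3a1 by 0.93 ± 0.21. The collagen I chains, among the brightest genes on the arrays, differed by -0.23 ± 0.15 for Col1a1 (adjusted p = 0.422) and -0.16 ± 0.10 for Col1a2 (adjusted p = 0.379). The fibronectin gene Fn1 rose by 0.35 ± 0.06 (adjusted p = 0.00899). Of 14 basement membrane genes, 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.365 with an estimated correlation), and Col4a1, a collagen IV chain, was 0.71 ± 0.17 higher. Among 30 matrix proteases and inhibitors, 7 rose and 3 fell, 11 and 4 adjusted over the list alone (camera adjusted p = 0.0213; adjusted p = 0.381 with an estimated correlation). The stromelysin gene Mmp3 rose by at least 3.37 and the collagenase gene Mmp13 by at least 2.13, while Adamts1 fell by 2.09 ± 0.28. Mmp2 and Timp1 differed by 0.34 and -0.52 with adjusted p = 0.170 and 0.161. The basement membrane list did not pass without Matrigel replicate 2 or plastic replicate 1 or 4 (adjusted p = 0.436, 0.0569 and 0.0625). The protease list did not pass without Matrigel replicate 2 or plastic replicate 4 (adjusted p = 0.131 and 0.0649). With only the plastic arrays of letters A and S the basement membrane and protease lists did not pass (adjusted p = 0.0824 and 0.228), nor with the macrophage list mean as a covariate (adjusted p = 0.232 and 0.299), both chosen after seeing the data. Mmp3 and Col12a1 did not pass without Matrigel replicate 1 (adjusted p from 0.0861 to 0.126). Mmp13 did not pass without Matrigel replicate 1 or plastic replicate 1, 2 or 4 (adjusted p from 0.0561 to 0.185). Loxl1 did not pass without Matrigel replicate 1 or 2 (adjusted p from 0.0719 to 0.0791). Col4a1 did not pass without Matrigel replicate 2 or plastic replicate 1, 2 or 4 (adjusted p from 0.0651 to 0.173). Col3a1 did not pass without Matrigel replicate 1 or plastic replicate 2, 3 or 4 (adjusted p from 0.0506 to 0.174). Col12a1, Loxl1, Col4a1, Col3a1 and Fn1 did not pass with the macrophage covariate (adjusted p from 0.0926 to 0.232), at 0.682 to 1.03 times the fitted differences. Mmp3, Mmp13, Col12a1, Loxl1, Col4a1, Col3a1 and Fn1 did not pass with only the plastic arrays of letters A and S (adjusted p from 0.0598 to 0.171), at 0.821 to 1.03 times the fitted differences. Col4a1 did not pass with only the arrays of Matrigel and plastic in the fit (adjusted p = 0.0591), at 1.00 times the fitted difference. Col3a1 did not pass with array weights (adjusted p = 0.0513), at 0.969 times the fitted difference. Mmp3 and Mmp13 lay at 0.792 and 0.690 times the fitted differences without Matrigel replicate 1. For Mmp3 this is 2.94, under the printed 3.37. Mmp3, Mmp13 and Col4a1 lay at 1.21, 1.31 and 0.656 times the fitted differences without Matrigel replicate 2.

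Of 29 retinoid and lipid storage genes, 13 rose on Matrigel and 2 fell, 14 and 4 adjusted over the list alone (camera adjusted p = 0.000203; adjusted p = 0.365 with an estimated correlation). Plin2, which coats lipid droplets, rose by 1.88 ± 0.12 (adjusted p = 0.000185), the fatty acid receptor gene Cd36 by at least 2.19 and the adipogenic regulator gene Pparg by 2.06 ± 0.38. A second probe set entry of Cd36, left out as the dimmer one with a mean of 2.78, differed by 1.20.  The retinal dehydrogenase gene Aldh1a2 fell by 2.34 ± 0.28. Lrat, which esterifies retinol for storage and was dim on Matrigel, did not pass (adjusted p = 0.567). Markers of other cell types moved with these genes. Of 27 macrophage markers 5 rose, 11 adjusted over the list alone, with a median difference of 1.04 (camera adjusted p = 5.91e-07; adjusted p = 0.365 with an estimated correlation), among them the integrin gene Itgam by 1.98 ± 0.48. The macrophage list mean was higher on Matrigel by 0.54 within letter A and by 0.48 within letter S, against an SD of 0.51 among the plastic arrays. Fry did not call the macrophage list (adjusted p = 0.102). Of 16 adipocyte markers, 6 rose, 8 adjusted over the list alone (camera adjusted p = 5.07e-06; adjusted p = 0.365 with an estimated correlation), although 6 of those 16 genes also stand in the lipid list. Itgam did not pass without Matrigel replicate 1 or 2, collagen replicate 1 or plastic replicate 1, 2 or 4 (adjusted p from 0.0516 to 0.156). Pparg did not pass without Matrigel replicate 2 (adjusted p = 0.0777). Itgam and Pparg did not pass with the macrophage covariate (adjusted p from 0.0883 to 0.145) or with only the plastic arrays of letters A and S (adjusted p from 0.0704 to 0.173), at 0.340 to 0.817 and 0.739 to 0.805 times the fitted differences. Cd36 lay at 1.18 times the fitted difference without Matrigel replicate 1. Cd36 lay at 0.823 times the fitted difference without Matrigel replicate 2.

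Pancreatic endocrine and exocrine markers were also higher on Matrigel. Of 18 islet markers 10 rose, 13 adjusted over the list alone, with a median difference of 1.32 (camera adjusted p = 2.14e-07; adjusted p = 0.365 with an estimated correlation). Iapp, the amylin gene of beta cells, rose by 3.46 ± 0.70, the granin gene Scg2 by 2.07 ± 0.43 and the glucose transporter gene Slc2a2 by at least 0.17. Of 29 acinar markers 4 rose, 9 adjusted over the list alone (camera adjusted p = 1.07e-06; adjusted p = 0.365 with an estimated correlation). Ctrb1, a chymotrypsinogen gene, was 3.80 ± 0.56 higher and the carboxypeptidase gene Cpa1 at least 1.63 higher. Of 19 duct and epithelial markers, 1 rose, 3 adjusted over the list alone with 1 lower (camera adjusted p = 0.00186; adjusted p = 0.365 with an estimated correlation). The gene past the threshold was Spp1, a secreted phosphoprotein that stellate cells also make, up by 2.87 ± 0.36. Without Matrigel replicate 1 the duct list did not pass (adjusted p = 0.0903). Iapp and Scg2 did not pass without Matrigel replicate 1 (adjusted p from 0.124 to 0.126). Iapp, Cpa1, Slc2a2 and Scg2 did not pass with the macrophage covariate (adjusted p from 0.0644 to 0.165) or with only the plastic arrays of letters A and S (adjusted p from 0.0704 to 0.120), at 0.919 to 1.13 and 0.806 to 0.972 times the fitted differences. Scg2 did not pass with only the arrays of Matrigel and plastic in the fit (adjusted p = 0.0554), at 1.00 times the fitted difference. Ctrb1, Cpa1, Slc2a2 and Scg2 lay at 0.698, 0.610, 0.632 and 0.660 times the fitted differences without Matrigel replicate 1. Ctrb1, Cpa1 and Scg2 lay at 1.30, 1.39 and 1.34 times the fitted differences without Matrigel replicate 2.

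Secreted signals and stress genes changed as well. Of 40 cytokine, chemokine and acute inflammatory genes, 10 rose and 2 fell, 14 and 4 adjusted over the list alone (camera adjusted p = 0.000480; adjusted p = 0.365 with an estimated correlation). Lif rose by 2.88 ± 0.18, the cyclooxygenase gene Ptgs2 by 2.70 ± 0.17 and the granulocyte growth factor gene Csf3 by 3.65 ± 0.52. Tgfb1, the profibrotic growth factor gene, rose by 1.76 ± 0.36 (adjusted p = 0.0169), while Il1rl1, which encodes the interleukin 33 receptor, fell by 4.39 ± 0.45 and the endothelin gene Edn1 by at least 3.08. Of 32 interferon-induced genes 10 fell, 20 adjusted over the list alone (camera adjusted p = 9.07e-09; adjusted p = 0.365 with an estimated correlation), Ifit1 by 2.65 ± 0.38. Of 20 cholesterol synthesis genes 11 fell, 13 adjusted over the list alone (camera adjusted p = 3.54e-07; adjusted p = 0.365 with an estimated correlation), Msmo1 by 1.27 ± 0.16. Of 27 NRF2 target genes 9 rose and 1 fell, 13 and 2 adjusted over the list alone (camera adjusted p = 0.000313; adjusted p = 0.365 with an estimated correlation). The cystine transporter gene Slc7a11 was 2.63 ± 0.44 higher. The cell cycle list was lower with 1 of 36 members past the threshold, Rrm2, which fell by 0.65 ± 0.14, also when adjusted over the list alone (camera adjusted p = 0.0133; adjusted p = 0.773 with an estimated correlation). Of 26 unfolded protein response genes Asns fell by 0.98 ± 0.15 and Dnajb9 rose by 0.52 ± 0.07, also when adjusted over the list alone (camera adjusted p = 0.0310; adjusted p = 0.529 with an estimated correlation). Without Matrigel replicate 2 the cell cycle list turned upward (adjusted p = 0.820), and without plastic replicate 2 or 4 it did not pass (adjusted p = 0.0718 and 0.0790). The unfolded protein response list did not pass without Matrigel replicate 1 or plastic replicate 1 or 3 (adjusted p = 0.547, 0.0684 and 0.0769). The cytokine and cell cycle lists did not pass with only the plastic arrays of letters A and S (adjusted p = 0.146 and 0.689) or with the macrophage list mean as a covariate (adjusted p = 0.491 and 0.981), both chosen after seeing the data. Rrm2 did not pass without Matrigel replicate 1 or 2 or plastic replicate 4 (adjusted p from 0.0502 to 0.118). Slc7a11 and Tgfb1 did not pass without Matrigel replicate 1 (adjusted p from 0.0523 to 0.135). Rrm2, Slc7a11 and Tgfb1 did not pass with the macrophage covariate (adjusted p from 0.0608 to 0.223), at 0.758 to 1.08 times the fitted differences. Rrm2 did not pass with only the plastic arrays of letters A and S (adjusted p = 0.0925) or with only the arrays of Matrigel and plastic in the fit (adjusted p = 0.0513), at 0.743 and 1.00 times the fitted difference. Il1rl1 and Slc7a11 lay at 1.17 and 0.714 times the fitted differences without Matrigel replicate 1. Il1rl1 and Slc7a11 lay at 0.831 and 1.29 times the fitted differences without Matrigel replicate 2. With only the plastic arrays of letters A and S 628 genes differed, without Matrigel replicate 1 759 and without plastic replicate 1 989.

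**Figure D1:**
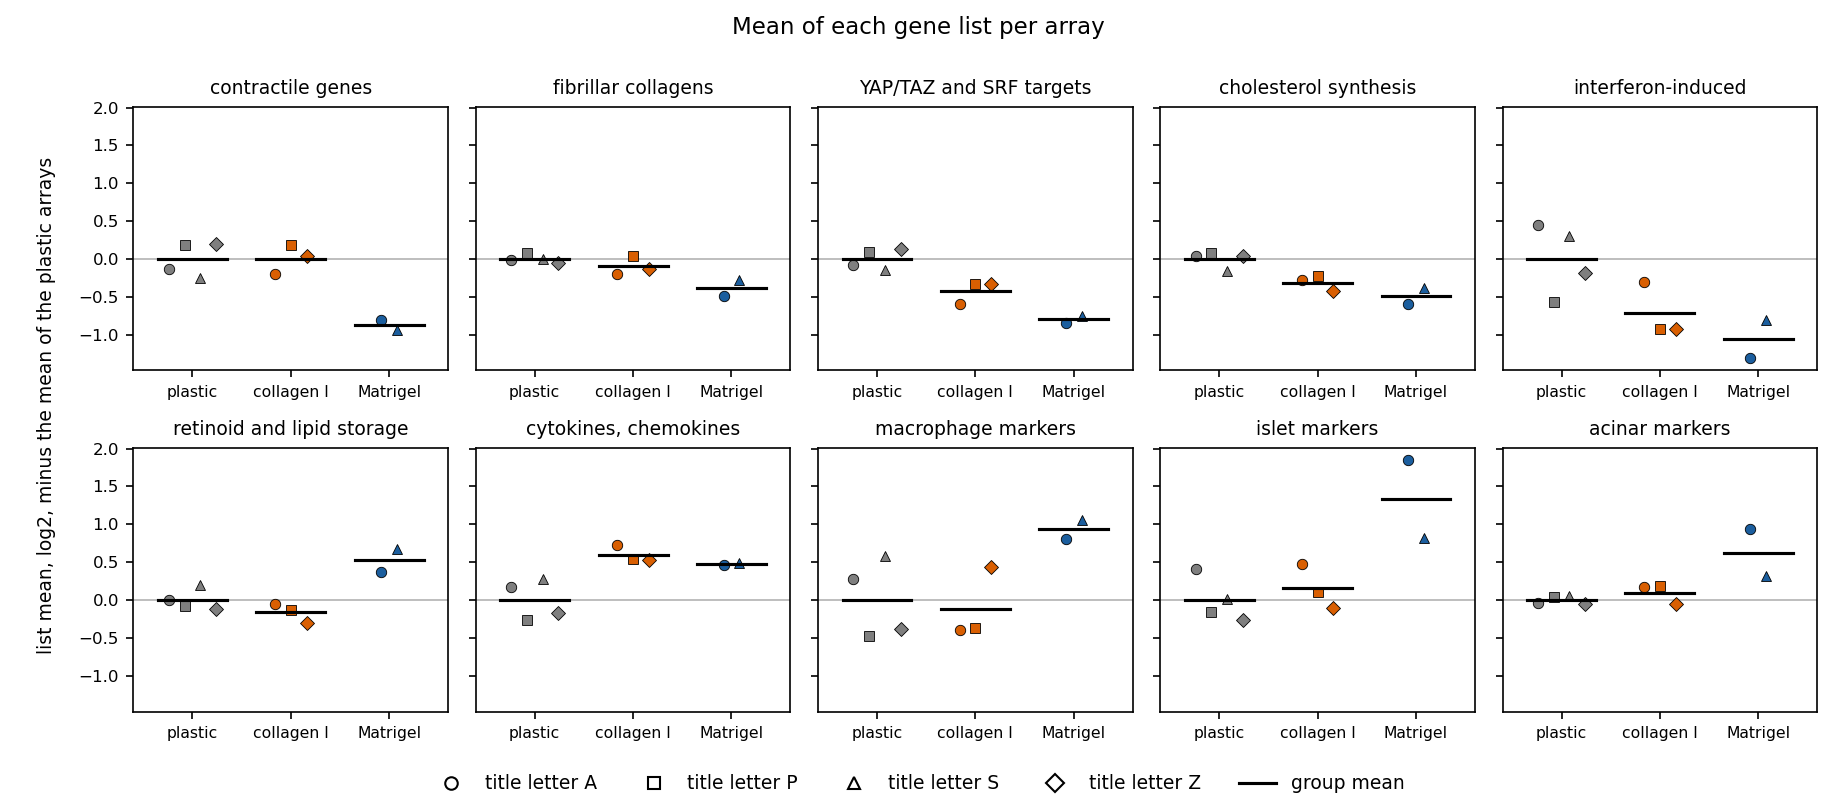
Mean log2 value of 10 gene lists on each of the 9 arrays, minus the mean of the 4 plastic arrays, by culture surface (horizontal axis). Points are arrays, the marker shape gives the title letter and the bar is the group mean; the contractile list lies at -0.81 and -0.94 on the Matrigel arrays against -0.25 to 0.20 on plastic, and the macrophage list at 0.81 and 1.06 against -0.48 to 0.58.

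Against plastic, of 40 cytokine, chemokine and acute inflammatory genes 12 rose on collagen I and 1 fell, and of 30 proteases and inhibitors 9 rose and 2 fell. Lif (Entrez gene 60584), a cytokine of the interleukin 6 family, averaged 10.01 ± 0.15 (SD, n = 3) on collagen I and 6.03 ± 0.24 (SD, n = 4) on plastic, a rise of 15.7-fold (adjusted p = 1.76e-05). Tgfb1 rose 5.30-fold (adjusted p = 0.00313). Il1rl1 (Entrez gene 25556) fell 22.1-fold (adjusted p = 0.000549) and Cd55, a brake on complement, 11.2-fold. In all, 888 genes differed between collagen I and plastic, 428 higher and 460 lower on collagen I, 316 of them by at least 2-fold. By camera with its preset correlation 7 of the 33 lists passed, 3 higher and 4 lower; with an estimated correlation camera called 0, and 1 had an unadjusted p under 0.05.

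Of 40 cytokine, chemokine and acute inflammatory genes, 12 rose on collagen I and 1 fell, 15 and 5 adjusted over the list alone (camera adjusted p = 6.12e-06; adjusted p = 0.650 with an estimated correlation). Besides Lif, Ptgs2 rose by 3.12 ± 0.15, Csf3 by 3.18 ± 0.45 and Il11 by 2.14 ± 0.15. Among 30 proteases and inhibitors 9 rose and 2 fell, 12 and 3 adjusted over the list alone (camera adjusted p = 0.00475; adjusted p = 0.650 with an estimated correlation). Mmp13 rose by at least 2.22, Mmp3 by at least 3.03 and Adamts4 by 1.82 ± 0.20. Of 27 other matrix genes 5 rose and 3 fell, 7 and 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.439; adjusted p = 0.862 with an estimated correlation). Among them Aspn, which encodes the small proteoglycan asporin, rose by 3.22 ± 0.58. The hyaluronan synthase gene Has2, in none of the lists, rose by 3.24 ± 0.38. The hepatocyte growth factor gene Hgf rose by 2.62 ± 0.19. Of 10 MHC class II genes, 3 were higher adjusted over the list alone although limma called 0 over all genes and 3 at an unadjusted p under 0.05. RT1-Da averaged 5.38 on collagen I and a dim 4.17 on plastic, and did not pass in limma (adjusted p = 0.0612). Nor did Cd74, at a difference of 1.87 ± 0.53 (adjusted p = 0.0858). This list was higher by camera (adjusted p = 0.0392; adjusted p = 0.650 with an estimated correlation), but not without collagen replicate 2 or 3 or plastic replicate 1 or 4 (adjusted p = 0.0713, 0.0626, 0.0555 and 0.0777). With the title letters as a block both genes passed, with adjusted p = 0.00937 for RT1-Da and 0.00250 for Cd74. Mmp13 did not pass without collagen replicate 2 or plastic replicate 1 or 4 (adjusted p from 0.0508 to 0.0640). Mmp3 did not pass without collagen replicate 1 or 2 or plastic replicate 4 (adjusted p from 0.0549 to 0.0756). Without collagen replicate 1 its difference was 2.85, under the printed 3.03. Aspn did not pass without collagen replicate 1 or 2 (adjusted p from 0.0509 to 0.0617). Mmp13 lay at 0.778 times the fitted difference without collagen replicate 1. Mmp13 and Mmp3 lay at 1.20 and 1.19 times the fitted differences without collagen replicate 3.

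Lower on collagen I were 8 of 20 YAP/TAZ and SRF targets, with 2 higher, and 12 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00294; adjusted p = 0.650 with an estimated correlation). F3 fell by 2.92 ± 0.38 and Amotl2 by 1.31 ± 0.13, while the immediate-early gene Fos rose by 2.53 ± 0.16. Of 20 cholesterol synthesis genes 6 fell, 8 adjusted over the list alone (camera adjusted p = 1.82e-05; adjusted p = 0.650 with an estimated correlation), with Msmo1 0.79 ± 0.14 lower. Of 32 interferon-induced genes 1 fell, Bst2 by 1.19 ± 0.24, and 13 did so adjusted over the list alone (camera adjusted p = 4.58e-06; adjusted p = 0.650 with an estimated correlation). Mx1, an antiviral GTPase gene, differed by -1.98 ± 0.56 (adjusted p = 0.0832; 0.00956 with the title letters as a block). Of 13 mesothelial markers 3 fell, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.650 with an estimated correlation), among them the transcription factor gene Wt1 by 1.02 ± 0.15. Without plastic replicate 3 this list did not pass (adjusted p = 0.0890). The dual oxidase gene Duox1 and its maturation factor gene Duoxa1 fell together, by 3.59 ± 0.48 and 2.94 ± 0.39. Bst2 did not pass without collagen replicate 2 or 3 or plastic replicate 1, 3 or 4 (adjusted p from 0.0599 to 0.0886). Msmo1 did not pass without collagen replicate 1 or 3 (adjusted p from 0.0510 to 0.0530).

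Of 26 contractile genes on collagen I, 2 fell and 1 rose, 3 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.779). Its median difference was -0.01 and the test pointed downward, while its mean lay slightly above 0. Des fell by 0.77 ± 0.12. Acta2 differed by 0.35 ± 0.34 (adjusted p = 0.668) and Col1a1 by 0.03 ± 0.13 (adjusted p = 0.931). Plin2 rose by 0.95 ± 0.11, whereas Pparg differed by 0.12 ± 0.33 (adjusted p = 0.889). The macrophage and islet lists did not pass (camera adjusted p = 0.779 and 0.555), with 1 of 27 and 0 of 18 members past the threshold in limma and 0 of each adjusted over the list alone, and with 3 and 0 at an unadjusted p under 0.05. Without collagen replicate 3 the macrophage list did pass (adjusted p = 0.0478). The macrophage list mean differed by -0.67, 0.10 and 0.81 within letters A, P and Z. The gene count was 552 without plastic replicate 1 and 555 without collagen replicate 2.

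Set against collagen I directly, 9 of 26 contractile genes fell on Matrigel, and of 29 lipid genes 7 rose and 1 fell. Tagln averaged 4.13 ± 0.05 (SD, n = 2) on Matrigel and 8.85 ± 0.72 (SD, n = 3) on collagen I, lower by at least 4.60 (adjusted p = 0.0138). Crip1 (Entrez gene 691657), which encodes a small LIM domain protein, fell 9.06-fold (adjusted p = 0.00582). Fabp4 was higher by at least 2.78 (adjusted p = 0.0148) and Gpd1 (Entrez gene 60666), a glycerol phosphate dehydrogenase gene, by at least 2.81 (adjusted p = 0.00635). Between these surfaces 387 genes differed, 176 higher and 211 lower on Matrigel, 98 of them by at least 2-fold; with each array re-centred on its median, 122 were higher and 259 lower. By camera with its preset correlation 14 of the 33 lists passed, 7 higher and 7 lower; with an estimated correlation camera called 0, and 4 had an unadjusted p under 0.05. Fabp4 lay at 1.26 times the fitted difference without Matrigel replicate 1. Fabp4 lay at 0.743 times the fitted difference without Matrigel replicate 2.

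Of 26 contractile genes 9 fell on Matrigel against collagen I, 20 adjusted over the list alone (camera adjusted p = 3.16e-13; adjusted p = 0.330 with an estimated correlation). Tpm2 fell by 2.59 ± 0.25 and Des by 1.16 ± 0.14, and Acta2 differed by -1.57 ± 0.41 (adjusted p = 0.0919). Of 28 fibrillar collagen genes 2 fell, 4 adjusted over the list alone (camera adjusted p = 0.000449; adjusted p = 0.571 with an estimated correlation), the cross-linking enzyme genes Lox by 0.67 ± 0.12 and Loxl3 by 0.62 ± 0.08. Of 34 TGF-beta and BMP pathway genes 6 fell, 11 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.479 with an estimated correlation), among them Bmp6 by 1.19 ± 0.19 and the BMP antagonist gene Grem1 by 1.44 ± 0.27. Tgfb1 differed by -0.65 ± 0.38 (adjusted p = 0.438). Of 20 YAP/TAZ and SRF targets 4 fell, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.571 with an estimated correlation), Fos by 2.32 ± 0.19. Of 27 other matrix genes 3 fell, 5 adjusted over the list alone, among them Mfap4 by 1.77 ± 0.25 and Fbln5 by 1.55 ± 0.27. This list did not pass (camera adjusted p = 0.0843; adjusted p = 0.600 with an estimated correlation), though it did without collagen replicate 3 or Matrigel replicate 2 (adjusted p = 0.0469 and 0.00598) and with the macrophage covariate (adjusted p = 0.00231). The interferon, cholesterol and cell cycle lists were lower by camera (adjusted p = 0.00883, 0.0193 and 0.000138; adjusted p = 0.716 for each with an estimated correlation), with 0 members past the threshold in limma over all genes or adjusted over the list alone and 5, 5 and 2 at an unadjusted p under 0.05. Without Matrigel replicate 1 the fibrillar, YAP/TAZ, interferon and cholesterol lists did not pass (adjusted p = 0.225, 0.142, 0.587 and 0.524). The interferon and cholesterol lists did not pass without collagen replicate 1 (adjusted p = 0.191 and 0.0719), nor the YAP/TAZ and cholesterol lists without collagen replicate 2 (adjusted p = 0.0969 and 0.0910). The cell cycle list did not pass without Matrigel replicate 2 (adjusted p = 0.621). With the macrophage list mean as a covariate, chosen after seeing the data, the YAP/TAZ, TGF-beta and cell cycle lists did not pass (adjusted p = 0.288, 0.157 and 0.749) and the cholesterol list turned upward (adjusted p = 0.914).

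Of 29 retinoid and lipid storage genes 7 rose on Matrigel against collagen I and 1 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 3.74e-07; adjusted p = 0.301 with an estimated correlation). Cd36 rose by at least 2.19, Pparg by 1.94 ± 0.40, the retinol carrier gene Rbp4 by 2.02 ± 0.35 and Plin2 by 0.93 ± 0.13. The dimmer entry of Cd36 differed by 1.05. Of 27 NRF2 targets 5 rose, 13 adjusted over the list alone (camera adjusted p = 1.78e-08; adjusted p = 0.242 with an estimated correlation), with Slc7a11 2.27 ± 0.46 higher. Macrophage markers were higher by a median of 1.21 (camera adjusted p = 3.21e-09; adjusted p = 0.546 with an estimated correlation). Of 27, 13 rose adjusted over the list alone and 0 in limma over all genes, with 15 at an unadjusted p under 0.05. Islet markers were higher by a median of 1.20 (camera adjusted p = 1.78e-08; adjusted p = 0.479 with an estimated correlation), 2 of 18 past the threshold and 12 adjusted over the list alone. Acinar markers (camera adjusted p = 1.49e-06; adjusted p = 0.546 with an estimated correlation) had 2 of 29 members higher, also when adjusted over the list alone, Ctrb1 and Cpa1. Adipocyte markers (camera adjusted p = 1.49e-06; adjusted p = 0.330 with an estimated correlation) had 3 of 16 higher, 8 adjusted over the list alone. The duct list was higher by camera (adjusted p = 0.0134; adjusted p = 0.585 with an estimated correlation) with 0 of 19 members past the threshold in limma by either adjustment and 6 at an unadjusted p under 0.05, but not without Matrigel replicate 1 (adjusted p = 0.524). Of the genes named as higher or lower here, Crip1, Des, Fos, Gpd1 and Tpm2 kept the call without each array in turn, and the others lost it without at least 1 (adjusted p up to 0.180). Ctrb1, Cd36, Cpa1, Slc7a11 and Rbp4 lay at 0.674, 1.19, 0.610, 0.668 and 1.30 times the fitted differences without Matrigel replicate 1. Ctrb1, Cd36, Cpa1, Slc7a11 and Rbp4 lay at 1.33, 0.811, 1.39, 1.33 and 0.696 times the fitted differences without Matrigel replicate 2. The gene count of this comparison moved with the setting, and the cause was not tested. Limma called 68 genes without collagen replicate 2 and 1 with the macrophage list mean as a covariate (added after seeing the data). With only the 5 arrays of these surfaces in the fit it called 0, where 2094 had an unadjusted p under 0.05. With that covariate, and with only these 5 arrays, 28 of the 28 calls of genes named in the text ended, at 0.659 to 1.31 times the fitted differences in the former and the same differences in the latter. Leaving out collagen replicate 1 or 3, Matrigel replicate 1 or 2, or plastic replicate 1, 2 or 4 gave 222, 192, 185, 255, 166, 241 and 221 genes.

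**Figure D2:**
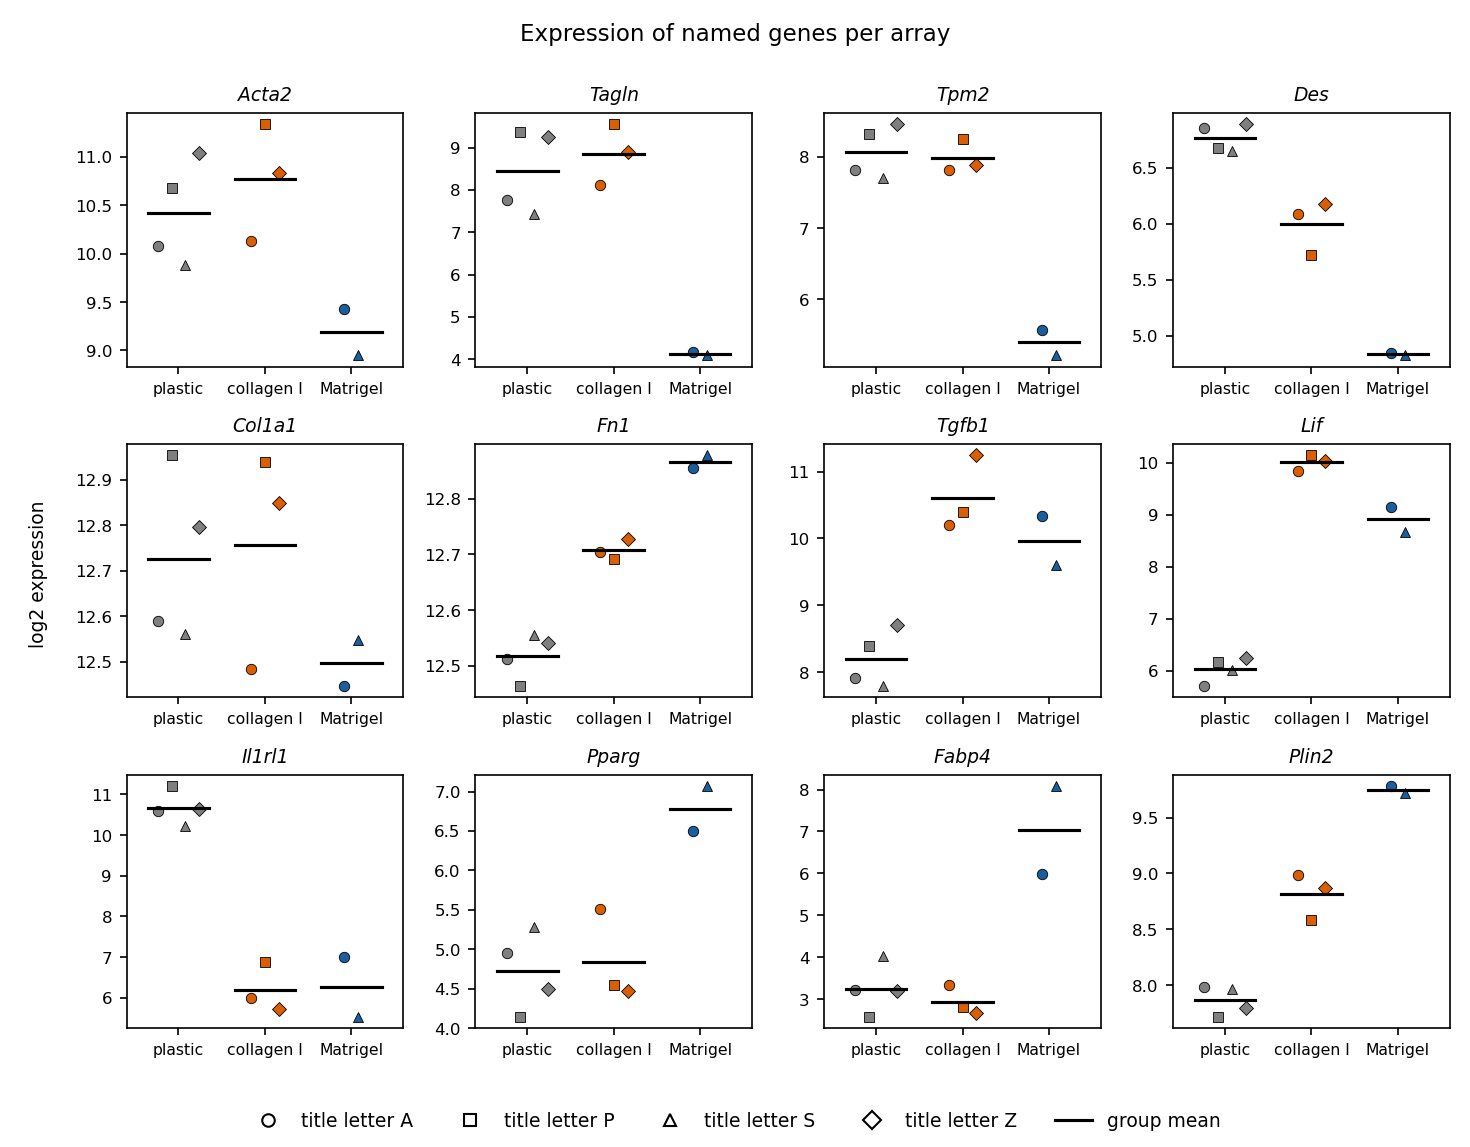
Log2 expression of 12 named genes on each of the 9 arrays by culture surface (horizontal axis); the vertical axes differ between panels and do not start at 0. Points are arrays, the marker shape gives the title letter and the bar is the group mean; Tagln averages 4.13 on Matrigel against 8.46 on plastic and 8.85 on collagen I, while Lif averages 8.92 on Matrigel and 10.01 on collagen I against 6.03 on plastic.

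Many genes differed from plastic on both matrices. In the comparisons of Matrigel and collagen I with plastic, 218 genes were higher in both and 293 lower in both, while 5 went in opposite directions. Rasd1, a dexamethasone-induced Ras gene, rose by 3.79 ± 0.28 on Matrigel and 3.87 ± 0.25 on collagen I, and the potassium channel gene Kcnd3 fell by at least 2.56 and 2.56. Il1rl1, Cd55, the Wnt antagonist gene Sfrp1 and the small heat shock protein gene Cryab fell on both, by 4.39, 4.64, 4.13 and 4.48 on Matrigel and by 4.46, 3.48, 3.42 and 3.16 on collagen I. Independent lists of these sizes would share 19.3 higher and 26.9 lower genes. The differences correlated across genes at r = 0.691, against 0.380 in 100 simulations of unchanged groups that shared the plastic arrays, and their covariance was 0.110 against 0.00815. With the plastic arrays split so that each comparison had its own 2, the shared count ranged from 222 to 330 over 6 splits and the covariance from 0.0811 to 0.110. Without Matrigel replicate 1 both comparisons shared 307 genes of like direction and without plastic replicate 1 332, against 511 with all arrays. Sfrp1 did not pass on collagen I without collagen replicate 1 or 3 or any 1 of the 4 plastic arrays (adjusted p from 0.0573 to 0.0910). On Matrigel Sfrp1 did not pass with the macrophage covariate (adjusted p = 0.105) or with only the plastic arrays of letters A and S (adjusted p = 0.0857), at 1.03 times the fitted difference in each. On Matrigel Il1rl1 and Sfrp1 lay at 1.17 and 0.580 times the fitted differences without Matrigel replicate 1. On Matrigel Il1rl1 and Sfrp1 lay at 0.831 and 1.42 times the fitted differences without Matrigel replicate 2. On collagen I Cryab lay at 0.802 times the fitted difference without collagen replicate 1.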

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

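All tests of explanations in this part except the regrouping of the arrays were chosen after the results were seen. In 5 series of 4 plastic values, 1 array lay far from the others: its gap to the nearest array, divided by the range of the series, was above Dixon's critical value. Chance gives this in about 1 in 20 series, and 120 series (87 genes and 33 list means) were examined. The share was 0.848 for Gfap, highest on plastic replicate 3 at 2.74 and near the floor of the arrays, and 0.951 for Lox, lowest there at 10.93. On plastic replicate 2 it was 0.936 for Spp1 (8.37, with the nearest array at 9.61), 0.858 for Il11 (4.72) and 0.892 for Wt1 (8.06), each the lowest of the group. No list mean met this criterion.

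Islet hormone transcripts were abundant and highest on Matrigel. The array of letter A had the highest islet list mean on 3 of 3 surfaces, which chance gives in 1 of 24 cases for a letter named in advance. Letter A was picked after the values were seen, so that share overstates how rare this is. Islet cells carried over from some preparations may account for that difference between letters, but the test does not say whether they account for the rise on Matrigel within letters. Ins1 averaged 11.76 on Matrigel, 10.73 on collagen I and 9.80 on plastic, and Gcg 10.79, 8.83 and 8.74; Ins1 and Ins2 probes can read each other. The smaller of the within-letter differences of the list mean, Matrigel minus plastic, was 0.81, against an SD of 0.30 among the plastic arrays. This argues against uneven title letters, though no within-letter difference has replicate arrays and letters were not read as pairs for Matrigel. Carried-over islet cells, their higher survival on Matrigel and a change in the stellate cells themselves were not separated.

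The lower contractile genes on Matrigel were also seen within letters, where the smaller difference of the list mean was -0.67 against an SD of 0.23 among the plastic arrays. Uneven letters are thus argued against, though here too no within-letter difference has replicate arrays and letters were not read as pairs for Matrigel. Dilution of stellate cell RNA by other cells would lower the stellate cell's other abundant transcripts by a like amount. Of the 28 genes of the fibrillar collagen list, 17 lay above the median difference of the whole contractile list, -0.69, by over 2 SE, and 4 lay below it by as much. This argues against dilution as the whole cause, while a smaller dilution beside another cause was not excluded, the fibrillar median being -0.23.

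Macrophages, which express Cd36 and Fabp4 too, may account for a part of the higher lipid genes on Matrigel. With the macrophage list mean as a covariate, 4 of the 13 risen genes of the lipid list still passed (Plin2, Rxra, Cd36 and Cebpa). The median difference of the 13 went from 1.65 to 1.34 and their median SE from 0.19 to 0.28, with 7 differences larger and 6 smaller than without it. The lipid list as a whole also passed by camera at the preset correlation with the covariate (adjusted p at most 0.0128). Most calls of the 13 ended, but without a common fall of the differences. The test cannot decide whether a larger share of macrophages was the whole cause, since the macrophage list was itself higher on Matrigel. The covariate's effect was thus set only by the spread within surfaces, over few arrays. A part for macrophages in the 6 whose differences became smaller, Cd36 and Fabp4 among them, was not excluded. Adipocytes among the cells stay open. The median difference of the 10 adipocyte markers outside the lipid list was 0.27 (upper quartile 0.89), as was that of the whole lipid list. The 2 of the 10 that passed, Cidec and Aqp7, were dim, with means of 3.15 and 2.76 over all arrays. Adipoq lay at 2.75 on Matrigel and 2.59 on plastic.

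Regrouping the 7 collagen and plastic arrays in all 35 ways gave a gene count as large as the real 888 in 1 split, the real one. The highest other count was 1 gene. This share lies under 0.05, but only if arrays may be exchanged freely across the letters. Of the 35, 8 part all 3 letter pairs of collagen and plastic as the real split does. The highest other gene count among the 8 was 1. Since 8 splits are too few for a share under 0.05, chance cannot be excluded for the gene count with the letter pairs kept. For the gene lists, 11 of the 35 splits gave as many lists as the real 7, the highest other split giving 13, so chance cannot be excluded for the number of lists. Of the 8 that part all 3 pairs, 2 did, the highest other giving 10, and the 27 that part fewer pairs gave up to 13. The split giving 10, which also gave the 1 gene, calls plastic replicates 1, 2 and 4 collagen. It thus holds the real contrast reversed, apart from plastic replicate 3, and is not a regrouping free of that contrast.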

How the results depend on the processing

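Fitting with only the plastic arrays of letters A and S, and with the macrophage covariate, was chosen after seeing the data. Gene counts within 1.5 times the reported ones came from re-centring, repeated quantile normalization, the filter on dim genes, every entry tested, trend and robust moderation and the random block in all 3 comparisons. Asking for a 2-fold difference gave 431 genes for Matrigel against plastic, 316 for collagen against plastic and 98 for Matrigel against collagen, fewer by construction. For Matrigel against plastic the count was 628 with only the plastic arrays of letters A and S, which leaves fewer arrays, and 466 with the macrophage covariate; leaving out 1 array gave 759 to 1461. For collagen against plastic leaving out 1 array gave 552 to 870. For Matrigel against collagen limma called 0 genes with only these groups in the fit (2094 at an unadjusted p under 0.05), 257 with array weights, 66 with the title letters as a fixed block, 1 with the macrophage covariate (1515 at an unadjusted p under 0.05) and 68 to 352 with 1 array left out. The cause was not tested. Without 1 Matrigel array the other is assumed to vary like the other groups.

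With an estimated correlation camera called 0 lists in the first comparison, 0 in the second and 0 in the third, at smallest adjusted p of 0.365, 0.650 and 0.242. Fry, which does not compare a list with other genes, called 15, 1 and 7, of which 11, 1 and 6 were among the reported ones. Between Matrigel and plastic fry ended the basement membrane, protease, cell cycle, unfolded protein response, duct and macrophage calls. Between collagen and plastic it kept only the cytokine call. The cell cycle list, lower on Matrigel than on plastic, had adjusted p from 2.36e-06 to 0.820 with 1 array left out, turning upward at the latter. Against collagen it turned upward with the title letters as a block (adjusted p = 0.924), as did cholesterol synthesis with the macrophage covariate (adjusted p = 0.914). The fixed block gave 1504 and 1072 genes in the comparisons with plastic, 14, 7 and 13 lists, of which 13, 7 and 9 were among the reported ones, and, of the collagen calls printed for genes in the report, changed only those of RT1-Da, Cd74 and Mx1; it also ended the collagen call of Dnajb9, which the report does not print (adjusted p = 0.0974). Between Matrigel and plastic the block ended the basement membrane, protease, cell cycle and cytokine calls (adjusted p = 0.110, 0.123, 0.460 and 0.104) and added the growth factor list (adjusted p = 0.0363). Between Matrigel and collagen it also ended the YAP/TAZ, TGF-beta and BMP, cholesterol and duct calls (adjusted p = 0.510, 0.0765, 0.141 and 0.0765). It added other matrix, proteases, cytokines and the unfolded protein response there (adjusted p = 0.000757, 0.0168, 6.33e-06 and 0.00229). Only genes above the dim level gave adjusted p = 0.0810 for the cell cycle and 0.140 for the unfolded protein response between Matrigel and plastic, and 0.103 for YAP/TAZ and 0.0578 for cholesterol between Matrigel and collagen. Genes called on both matrices numbered 237 in the median of the plastic splits, which leave fewer controls, and 307 to 472 with 1 array left out. The cause was not tested. Of the genes the text names, 54, 38 and 28 were called in the comparisons in turn; 40, 31 and 7 of them passed without each array in turn. Of the same calls the macrophage covariate ended 17, 1 and 28, the title letters as a fixed block 1, 1 and 16, and only the plastic arrays of letters A and S 16 in the first comparison. In that comparison the differences of the ended calls had medians of 0.950 times the fitted ones with the covariate and 0.948 times with only those plastic arrays; 0 changed direction under any alternative run. Dim genes, near log2 4.25 and below, carry little signal over background.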

Other observations

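Of 32 growth factors and their receptors, 2 rose and 7 fell on Matrigel against plastic, and 1 rose and 8 fell on collagen I. Adjusted over the list alone, 2 rose and 8 fell on Matrigel and 2 rose and 10 fell on collagen I. The list did not pass in either (camera adjusted p = 0.0669 and 0.102; adjusted p = 0.365 and 0.650 with an estimated correlation), though fry called it on Matrigel (adjusted p = 0.0128). It passed on Matrigel without collagen replicate 3 or Matrigel replicate 2 (adjusted p = 0.0397 and 0.0304) and on collagen I without collagen replicate 2 (adjusted p = 0.0337). On collagen I the test pointed downward and the mean was -0.42, with a median near 0. Hgf rose by 2.20 ± 0.21 on Matrigel and by 2.62 ± 0.19 on collagen I, and Fgf7, a keratinocyte growth factor gene, by 0.76 ± 0.09 and 0.87 ± 0.08. Fgf18 fell by 2.44 ± 0.19 on Matrigel and by 1.90 ± 0.17 on collagen I, and Igfbp3, which binds insulin-like growth factors, fell by 2.28 ± 0.20 and by 1.76 ± 0.17. Bmp6 fell by 2.97 ± 0.18 and by 1.78 ± 0.16. Of 23 integrins and collagen receptors 3 rose and 2 fell on Matrigel, 3 and 3 adjusted over the list alone, and 2 rose and 3 fell on collagen I, 5 and 3 adjusted over the list alone. The list did not pass (camera adjusted p = 0.741 and 0.231; adjusted p = 0.780 and 0.650 with an estimated correlation). The collagen receptor gene Ddr1 fell by 1.91 ± 0.22 on Matrigel and by 1.82 ± 0.20 on collagen I, while the fibronectin receptor gene Itga5 rose by 1.30 ± 0.26 and 1.40 ± 0.23. On Matrigel Itga5 did not pass without Matrigel replicate 1 (adjusted p = 0.123), with the macrophage covariate (adjusted p = 0.142) or with only the plastic arrays of letters A and S (adjusted p = 0.0618), the latter 2 at 0.950 and 1.12 times the fitted difference.

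Of 13905 entries of the value table with no gene symbol or with several, tested together with the others, 759 differed between Matrigel and plastic, 310 between collagen and plastic and 189 between Matrigel and collagen.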
